A study of Mus musculus with 2 samples.

How the data were processed

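Total RNA of mouse embryonic hindbrain at embryonic day 13.5 was the input of 2 libraries, which the labels number as biological replicates 1 and 2. Each was made from 10 ng of RNA longer than 200 nt, extracted with the Ambion mirVana method from pooled male and female embryos of strain B6NCrl, with a SMARTer Ultra Low kit manual among the cited protocols, per the labels. ERCC spike-ins, synthetic RNAs added at known amounts, were included. Both libraries carry the same donor label and different biosample labels, and the spread between them may be partly technical. The libraries form 1 group, so the design holds no contrast between groups.

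The authors deposited a gene table and a transcript table per library. The estimated counts (expected counts, not whole numbers) are reads assigned to each gene by the authors from transcriptome alignments, per the file headers. TPM values, as deposited by the authors, are relative to all rows of a library, spike-ins included. The authors also deposited FPKM, a posterior mean TPM and the lower and upper bounds of a credibility interval of TPM and of FPKM. The level of these intervals is not stated in the files, and they surround the posterior mean, so that a TPM can lie outside its own interval. The percent of a gene's TPM carried by each transcript was deposited as well by the authors. The assembly was mm10 with GENCODE annotation M4, per the notes deposited with the files. The aligner, the counting program, their versions and the strand setting are not given in the sources used here. A gene and its antisense or overlapping partner are therefore treated as uncertain, as are near-identical copies.

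The tables hold 69691 rows, of which 43346 are Ensembl genes, 96 are ERCC spike-ins, 1 is phiX and 26248 have only a number as identifier. Names, positions and gene types were taken from GENCODE M21 on GRCm38, the same build as mm10, by identifier without version; 42462 of the Ensembl genes matched and 884 did not. The unmatched genes held 0.202% and 0.205% of the Ensembl gene counts of replicates 1 and 2. Apart from the spike-in values, all comparisons used the Ensembl genes. The totals were 33080194 estimated counts in replicate 1 and 38756411 in replicate 2. Limits cover counting error only. The deposited intervals can be wider where reads are shared between near-identical genes: Rn7s1 in replicate 1 ran from 6082 to 22776 TPM on 56873 counts. Neither covers the spread between samples, and reads without molecular identifiers are not independent molecules.

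Levels were compared as log2(TPM + 1), which understates differences between genes of low level. A gene was called detected at a TPM of 1 or more in both libraries. Per value, the mean and SD over the 2 libraries are given. Estimated counts were rounded to whole numbers before count methods. Normalization factors (TMM) and a common biological coefficient of variation were computed with edgeR 4.0.16 in R 4.3.3 from an intercept-only design, since no quasi-likelihood test can be run on 1 group. A two-sided exact binomial test of each gene's counts, given the effective library sizes, was run with SciPy 1.17.1 on genes with at least 10 counts in the pair, with Benjamini-Hochberg adjustment at 0.05. That test compares 2 libraries, not conditions, and its p-values measure counting error only, not the spread between samples. DESeq2 1.42.0 gave an alternative dispersion. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

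Before the data were examined, 34 gene lists for regions, cell types and RNA classes were fixed, with 351 symbols of which 348 matched a gene. A list's median was set beside 10000 random lists of the same size, drawn for levels from the 25474 genes with a count in either library, and for the ratio of replicate 2 over replicate 1 from genes matched on mean expression in 20 bins. These percentiles describe the 2 libraries and are not tests across animals. Members with a mean TPM of 1 or more entered the ratios, and lists with fewer than 3 such members were left out. The named genes were also set by rule: the 3 highest and the lowest detected member of each list, any Hox gene, all sex chromosome and isoform genes, the 15 genes with the highest mean TPM, and the 10 with the greatest change between the libraries among genes with a mean TPM of 5 or more and disjoint intervals. Genes of the lists used to weigh an explanation are named as well, and some genes that the rule names are not reported here.

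The methods were tested on simulated data. The common biological coefficient of variation was recovered as 0.0499, 0.0996 and 0.196 where 0.05, 0.1 and 0.2 had been simulated over 43346 genes. The binomial test, on counts without replicate spread over 19684 genes, called 99.0% of 100 genes raised 2-fold, 59.0% of 100 genes raised 1.2-fold and 10 unchanged genes. Of 200 simulated lists of 10 genes without a shift, 7.0% lay outside the central 95% of random lists, and all of 100 lists shifted by 0.5 did. Smaller shifts, such as most of those reported below, and lists of other sizes were not part of this test.

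Alternatives were other pseudocounts, filters, FPKM, the posterior mean TPM, other library scalings, list means, other transcript filters and each library alone. Removal of a linear trend on gene length, GC content and expression was added after the data were seen, as was a comparison with the 50 genes nearest to each list member in these 3 properties. GC content was known for 99.2% of the genes in that fit.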

Results

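The hindbrain of the mouse embryo at day 13.5, which gives rise to the cerebellum, pons and medulla, was profiled by RNA sequencing. Total RNA was the input of the 2 libraries, labelled as biological replicates. Replicate 1 held 33080194 estimated counts and replicate 2 held 38756411. A TPM of 1 or more was reached in both libraries by 15342 Ensembl genes, of which 13364 are annotated as protein coding, 471 as processed pseudogenes, 372 as antisense and 288 as long intergenic noncoding. Replicate 1 alone had 15876 such genes and replicate 2 had 15883. Values below are the mean TPM ± SD with n = 2 unless each library is named. With a single group there is no contrast between conditions, and the comparisons are between gene groups within the tissue and between the 2 libraries.

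The 15 genes with the highest mean TPM were of several kinds. Tuba1a, an alpha-tubulin of developing neurons, stood first at 13900 ± 446 TPM (SD, n = 2). Malat1, a nuclear noncoding RNA, had 10070 ± 787, Actb, a cytoskeletal actin, 6251 ± 134, Stmn1, a microtubule regulator, 5628 ± 15.1, Tmsb4x, an actin-binding peptide, 5318 ± 114, and Nnat, an imprinted neuronal gene, 5107 ± 305 (SD, n = 2). Ftl1, the ferritin light chain, reached 5738 ± 39.7 and Hba-a2, an alpha-globin of red blood cells, 5156 ± 310 (SD, n = 2). The signal recognition particle RNAs Rn7s1 and Rn7s2 are near-identical copies whose reads cannot be told apart; together they had 27610 ± 302 TPM (SD, n = 2), while the interval of Rn7s1 in replicate 1 ran from 6082 to 22776. Gm28437 on chromosome 1 (24613189 to 24613971, an unprocessed pseudogene) resembles mitochondrial sequence and had 9148 ± 476 TPM (SD, n = 2). Which mitochondrial gene it copies was not determined. Its interval in replicate 1 ran from 2334 to 9528. The mitochondrial gene mt-Atp6, a subunit of ATP synthase, had 7415 ± 404 TPM (SD, n = 2). mt-Atp8, another subunit, had 6527 ± 82.2 and the ribosomal RNA mt-Rnr2 had 5010 ± 82.9 (SD, n = 2). Gm22133, annotated as a microRNA, had 4735 ± 806 TPM (SD, n = 2). Its position on chromosome 7 (45458089 to 45458197) lies within Ftl1 (45457944 to 45459884), so the reads may belong to either. Its TPM rested on 1096 and 1016 counts in replicates 1 and 2, against 102713 and 120095 for Ftl1. The span of Gm22133 is also below the minimum RNA length of the libraries. TPM is divided by length, so its place among the highest genes depends on that short span.

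Mitochondrially encoded genes took 3.53% ± 0.00682 of TPM, ribosomal protein genes 4.17% ± 0.0685, haemoglobin genes 1.35% ± 0.0748 and the 10 highest genes 9.23% ± 0.192 (SD, n = 2). As shares of estimated counts, which are not divided by length, these were 1.80%, 1.53%, 0.430% and 5.25%. The mitochondrial share leaves out reads assigned to Gm28437, which resembles mitochondrial sequence and had 9148 ± 476 TPM (SD, n = 2). Spike-ins took 5.50% of TPM in replicate 1 and 5.99% in replicate 2, and 2.43% of estimated counts on average. Of the 96 spike-in sequences 83 and 82 had a count, and across spike-ins the Pearson correlation of log2(TPM + 1) between the libraries was 0.999. The 8 widely expressed genes, led by Actb, Ppia, a peptidyl-prolyl isomerase, at 3264 ± 14.2 and Eef1a1, a translation elongation factor, at 2955 ± 18.97 (SD, n = 2), were all detected; Tbp, the TATA-binding protein, was the lowest at 47.7 ± 3.42 (SD, n = 2). All 9 matched long noncoding RNAs were detected, among them Meg3, a maternally expressed imprinted transcript, at 1388 ± 101 and Snhg11, which the annotation used here lists as protein coding, at 435 ± 36.6, with Neat1, a scaffold of nuclear paraspeckles, lowest at 2.53 ± 0.198 (SD, n = 2). Of 4 non-polyadenylated structured RNAs 3 were detected. Rn7sk, a regulator of transcription elongation, had 381 ± 27.8, Rpph1, the RNA of ribonuclease P, 99.7 ± 6.85 and Rmrp 6.08 ± 1.25 (SD, n = 2). How fully the library protocol captures RNAs without a poly(A) tail was not tested, so these are levels in the libraries, not in the tissue.

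The regional identity of the dissected tissue was read from transcription factors of the hindbrain and forebrain. Of 20 hindbrain factors 19 were detected, led by Meis1 at 173 ± 0.325, Meis2 at 128 ± 21.3 and Pbx3 at 108 ± 0.0424 (SD, n = 2), homeodomain partners of Hox proteins. Phox2a, a determinant of noradrenergic and cranial motor neurons, was the lowest at 1.75 ± 0.255 (SD, n = 2). Of 19 forebrain factors 3 were detected: Neurod6 at 57.9 ± 9.97, Foxd1 at 1.46 ± 0.347 and Dlx5 at 1.30 ± 0.368 (SD, n = 2). Neurod6, a neuronal bHLH factor, therefore stood among the hindbrain factors in level. The median of the hindbrain list exceeded that of the forebrain list by 3.97 ± 0.164 on the log2(TPM + 1) scale (SD, n = 2). The size of this difference depends on the added 1, since the forebrain median was 0.30 TPM, and it was 5.61 with a pseudocount of 0.1.

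Genes of the neighbouring midbrain and of its border with the hindbrain were present at intermediate levels. Gbx2, which sets the anterior limit of the hindbrain, had 44.9 ± 0.120, Pax2 14.0 ± 0.113 and Lmx1b 5.28 ± 0.212 (SD, n = 2), and Wnt1, a signal of the border, was the lowest of the 7 of 9 detected border genes at 3.38 ± 0.537 (SD, n = 2). In the midbrain list 7 of 10 genes were detected, led by Pou4f1, also a marker of sensory neurons, at 67.9 ± 0.509, Nr4a2 at 22.1 ± 1.70 and Otx2, a forebrain and midbrain determinant, at 18.3 ± 0.7 (SD, n = 2); Otx1 was the lowest at 1.49 ± 0.276 (SD, n = 2).

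The axial level of the tissue was read from the Hox genes, whose expression domains follow their order along the chromosome. Paralog groups 1 to 4 had 11 of 12 genes detected, groups 5 to 8 had 9 of 11, and groups 9 to 13 had 1 of 16, Hoxb9 at 4.90 ± 1.42 TPM (SD, n = 2). Hoxb5 was the highest Hox gene at 168 ± 10.9, followed by Hoxa5 at 108 ± 19.3, Hoxb6 at 87.2 ± 28.6, Hoxc4 at 66.3 ± 6.04, Hoxd3 at 64.2 ± 3.59, Hoxb2 at 34.9 ± 4.88 and Hoxa2 at 33.4 ± 0.721 (SD, n = 2). The median of groups 1 to 4 lay 3.60 ± 0.0662 above that of groups 9 to 13 on the log2(TPM + 1) scale, or 6.75 with a pseudocount of 0.1, since the median of groups 9 to 13 was 0.005 TPM. It lay 0.71 below that of groups 5 to 8, a difference of -0.71 ± 0.28 (SD, n = 2). The last difference was -0.51 in replicate 1 and -0.91 in replicate 2, and -0.28 with CPM, which is not divided by gene length. No count fell on 8 genes of groups 9 to 13 in either library, which allows up to 0.156 TPM in replicate 1 and 0.132 TPM in replicate 2 at 3 counts. The deposited interval of Hoxa13, 1 of these genes, reached further, to 0.638 and 0.539 TPM.

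**Figure D1:**
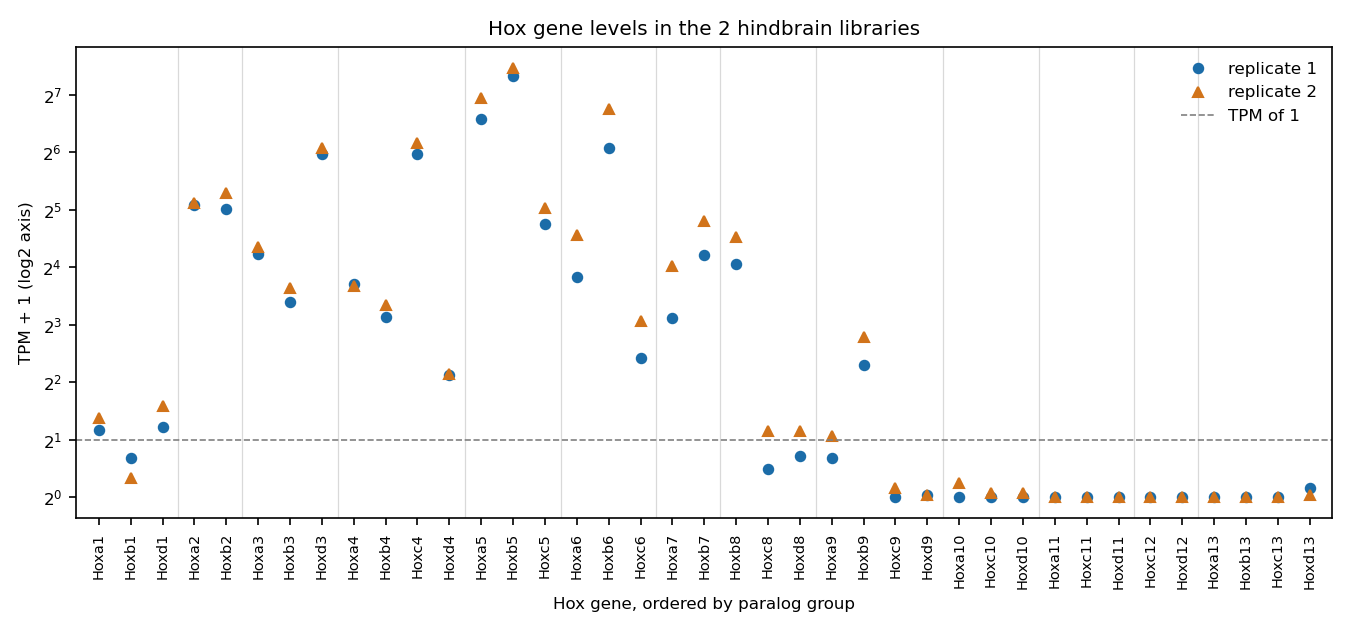
The TPM + 1 of each Hox gene is plotted on a log2 axis in order of paralog group, with circles for replicate 1 and triangles for replicate 2 and a dashed line at a TPM of 1. Hoxb5 is the highest at 160 and 175 TPM, and of groups 9 to 13 only Hoxb9 lies above the line in both libraries, at 3.89 and 5.90 TPM.

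Genes of dorsal and ventral hindbrain territories were both present. In the list of the cerebellar anlage and rhombic lip, the dorsal source of granule neurons and precerebellar neurons, 15 of 17 genes were detected, with Zic4 at 40.8 ± 8.80, Foxp2 at 38.9 ± 4.38, Pax6 at 22.8 ± 1.97 and the lowest, Barhl2, at 1.41 ± 0.163 (SD, n = 2). Atoh1, the bHLH factor that marks the rhombic lip, had 11.4 ± 7.11 (SD, n = 2). Of 12 ventral patterning genes 9 were detected, led by Dbx1 at 17.5 ± 8.32, Nkx6-2 at 10.5 ± 2.04 and Nkx6-1 at 7.18 ± 1.17, homeodomain factors of progenitor domains, down to Shh, the floor plate signal, at 1.48 ± 0.113 (SD, n = 2).

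Postmitotic neuron genes had a higher list median than neural progenitor genes in both libraries. All 16 postmitotic neuron genes were detected. They included Tubb3, a neuronal beta-tubulin, at 1509 ± 48.1, Stmn2 at 890 ± 29.9 and Gap43, a growth cone protein, at 830 ± 32.7, and Rbfox3 lowest at 44.1 ± 0.446 (SD, n = 2). Of 14 neural progenitor genes 13 were detected, led by Fabp7, a radial glia fatty acid binding protein, at 1915 ± 180, Dbi at 1000 ± 146 and Vim, an intermediate filament, at 613 ± 17.4, with Sox1 lowest at 1.78 ± 0.255 (SD, n = 2). The list medians differed by 2.87 ± 0.0477 on the log2(TPM + 1) scale (SD, n = 2). All 18 cell cycle genes were detected, from Pcna, the replication clamp, at 95.1 ± 2.67, Cdk1 at 85.6 ± 7.74 and Rrm2 at 65.8 ± 10.6 down to Mki67 at 7.19 ± 0.933 (SD, n = 2).

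Transmitter genes of several neuron classes were detected. Slc17a6, the vesicular glutamate transporter VGLUT2, had 57.5 ± 1.72 and Slc17a8, its relative VGLUT3, 2.25 ± 1.03 (SD, n = 2), the 2 detected of 3 glutamatergic genes. All 6 GABAergic and glycinergic genes were detected. They included the GABA-synthesizing enzymes Gad2 at 52.2 ± 2.96 and Gad1 at 40.1 ± 0.481, and the vesicular transporter Slc32a1 lowest at 6.02 ± 0.905 (SD, n = 2). The log2 ratio of Slc17a6 over the mean of Gad1 and Gad2 was 0.32 ± 0.08 (SD, n = 2), and 0.91 with CPM. Of 9 cholinergic and motor neuron genes 8 were detected, with Prph, a peripheral neuron filament, at 54.3 ± 8.33, Isl1 at 38.7 ± 5.14 and Chat, which makes acetylcholine, at 1.41 ± 0.170 (SD, n = 2). All 10 serotonergic and noradrenergic genes were detected, led by Gata3 at 37.3 ± 15.7, Maoa, a monoamine oxidase, at 14.6 ± 0.00707 and Gata2 at 13.0 ± 3.54, with Slc6a2, the noradrenaline transporter, at 1.55 ± 0.771 (SD, n = 2).

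Glial and vascular gene lists had lower medians than the neural progenitor list, at 45.3 TPM, while the erythroid list had a higher one. All 10 oligodendrocyte lineage genes were detected, with Cldn11 at 43.1 ± 0.926, Cnp at 29.0 ± 1.51, Olig1 at 20.6 ± 4.497 and the myelin protein gene Mog at 1.39 ± 0.516 (SD, n = 2). Of 8 astrocyte genes 6 were detected, with Aldoc at 131 ± 17.8, Gja1 at 81.3 ± 7.96, Aldh1l1 at 35.9 ± 0.170 and the water channel gene Aqp4 at 1.33 ± 0.240 (SD, n = 2). The undetected astrocyte genes were Gfap at 0.12 ± 0.0283 and Aqp9 at 0.27 ± 0.198 (SD, n = 2). The 10 microglia genes were all detected, with the complement genes C1qb at 35.1 ± 6.03 and C1qa at 19.6 ± 0.502, Tyrobp at 27.6 ± 4.59 and Trem2 at 4.38 ± 0.615 (SD, n = 2). All 8 endothelial genes, with the tight junction gene Cldn5 at 73.9 ± 3.95, Esam at 34.4 ± 1.25, Kdr at 20.3 ± 0.849 and Tek at 7.43 ± 0.283, and all 6 pericyte genes, with Pdgfrb at 15.4 ± 0.559, Rgs5 at 11.8 ± 0.665, Kcnj8 at 10.4 ± 0.622 and Anpep at 1.96 ± 0.149, were detected (SD, n = 2). The 10 erythroid genes had the second highest list median at 791 ± 63.5 TPM (SD, n = 2), with Hba-a2 at 5156 ± 310, the embryonic globin Hbb-y at 3373 ± 78.6 and Hba-a1 at 2046 ± 119 (SD, n = 2). Hba-a1 and Hba-a2 are close copies and summed to 7202 ± 429 (SD, n = 2).

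Genes of tissues bordering the hindbrain were also measured. Choroid plexus genes, which mark the secretory epithelium of the ventricle roof, were detected in 9 of 10 cases, with the thyroid hormone carrier Ttr at 777 ± 346, Enpp2 at 55.4 ± 8.004 and Kcne2 at 29.4 ± 15.5 (SD, n = 2). All 10 meningeal and mesenchymal genes were detected, with the collagens Col3a1 at 253 ± 34.3, Col1a1 at 140 ± 50.9 and Col1a2 at 135 ± 27.2 and the lowest, Foxd1, at 1.46 ± 0.347 (SD, n = 2). Detected members numbered 4 of 9 for skeletal muscle, with Actc1 at 39.1 ± 3.71, Acta1 at 6.97 ± 1.49 and Myog at 3.02 ± 0.106 (SD, n = 2). They were 3 of 7 for cartilage, with Col2a1 at 49.97 ± 9.39, Col9a2 at 11.3 ± 0.898 and Col9a1 at 7.73 ± 4.12 (SD, n = 2). The undetected cartilage genes were Matn1 at 1.07 ± 0.686 (0.58 in replicate 2), Matn3 at 0.38 ± 0.283, Acan at 0.315 ± 0.191 and Comp at 0.21 ± 0.170 (SD, n = 2). Whether the detected members reflect cartilage was not tested. Of 7 epithelial genes 4 were detected, with the keratins Krt18 at 9.09 ± 3.86 and Krt8 at 4.53 ± 1.34, Epcam at 2.66 ± 0.453 and Cdh1 at 1.64 ± 0.339 (SD, n = 2). All 8 matched sensory ganglion genes were detected, led by Pou4f1, Prph and Isl1, with the sodium channel gene Scn10a at 1.27 ± 0.156 (SD, n = 2). Of 10 immediate early and heat shock genes 8 were detected, with Jun at 45.7 ± 0.764, Dusp1 at 28.5 ± 0.530, Ier2 at 23.7 ± 3.47 and Atf3 at 1.11 ± 0.149 (SD, n = 2). In 30 of the 34 lists the detected members were no fewer than the others.

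**Figure D2:**
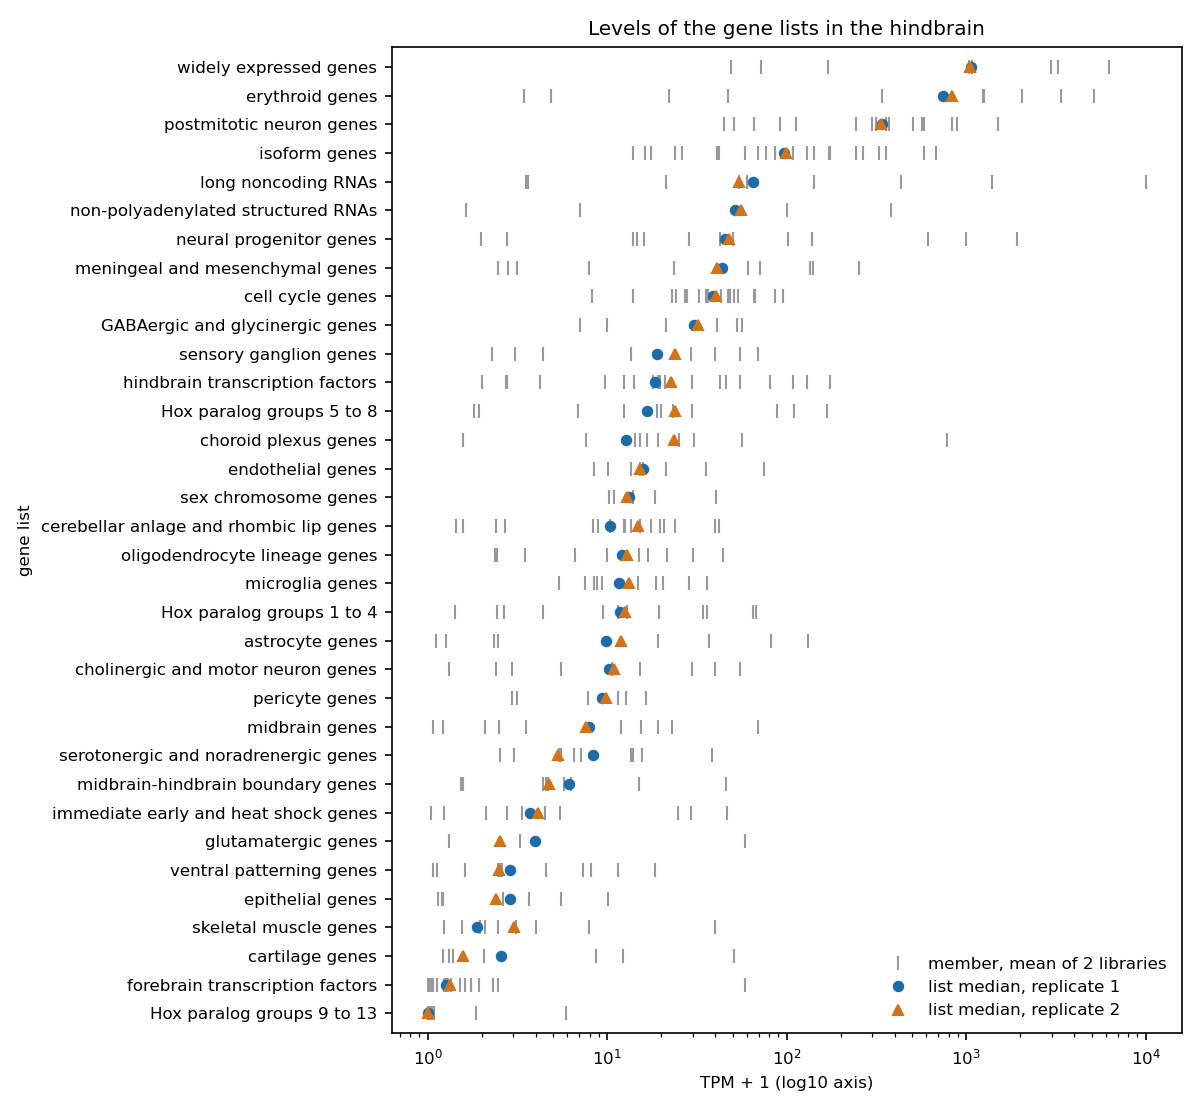
The TPM + 1 of list members is plotted on a log10 axis for the 34 gene lists, with ticks for members (mean of 2 libraries) and circles and triangles for the list median in replicates 1 and 2. The postmitotic neuron list has a median of 336 TPM, the neural progenitor list 45.3 and the forebrain transcription factor list 0.30.

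Agreement of the replicates was measured across genes. Over 15878 genes with a mean TPM of 1 or more, the Pearson correlation of log2(TPM + 1) was 0.987 and the Spearman correlation 0.989; these are correlations across genes, which are not independent replicates. The common biological coefficient of variation was 6.09% in edgeR, and 0.01% from the median gene-wise dispersion of DESeq2, the lower bound of that tool. A difference of 2-fold or more between the libraries occurred in 234 of these genes, 123 higher in replicate 2 and 111 lower. The number was 46 among the 11500 genes with a mean TPM of 5 or more. It was 50 with CPM, where the added 1 shrinks differences of genes with few counts. From 1 to 5 TPM 4.29% of genes differed 2-fold, and from 20 to 100 TPM 0.117% did. The deposited credibility intervals, of unstated level, were disjoint for 1472 genes, 707 higher in replicate 2 and 765 lower; with replicate 2 rescaled by the median log2 ratio the split was 846 higher and 600 lower. The exact binomial test called 2390 of 19687 genes at an adjusted p of 0.05, 1349 higher and 1041 lower; it sets the difference between these 2 libraries against counting error alone.

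The 10 genes with the greatest change among those with a mean TPM of 5 or more and disjoint intervals held 3 choroid plexus genes, Kcnj13, Kcne2 and Clic6. Kcne2, a potassium channel subunit (ENSMUSG00000039672.8) on chromosome 16 (92292389 to 92298129), had 18.5 TPM in replicate 1 and 40.4 in replicate 2 (adjusted p = 6.5e-65, exact binomial test of the 2 libraries), and Kcnj13, another channel subunit, had 11.2 and 25.3 (adjusted p = 2.5e-29, the same exact test). Atoh1 (ENSMUSG00000073043.4), on chromosome 6 of mm10 (64729125 to 64731245), had 6.35 and 16.4 (adjusted p = 2.6e-44, exact binomial test). Fgf3, a growth factor expressed in the hindbrain, had 10.9 and 24.2, and Clic6 3.92 and 9.35. Lower in replicate 2 were Lhx3, a factor of motor and V2 interneurons on chromosome 2 (26200212 to 26208289), with 12.5 and 4.26 TPM (adjusted p = 2.7e-39, exact binomial test), and the collagen gene Col16a1, with 11.7 and 4.65. The log2 ratio of Col16a1 was -1.17, and -0.74 with CPM, and its TPM in replicate 2 lay below its own interval of 5.08 to 7.95. Gm24407, annotated as a small nuclear RNA, had 4.61 and 18.5 TPM on 4 and 19 counts (adjusted p = 0.06, exact binomial test). Its log2 ratio was 1.80, and 0.42 with CPM. The 1 added to CPM shrinks the ratio of so few counts, so the lower value does not show a smaller change. Gm27477, a short RNA within the Hoxa region of chromosome 6, had 23.1 and 51.2 TPM on 21 and 55 counts (adjusted p = 0.016, exact binomial test). Its span (52162125 to 52162267) is below the minimum RNA length of the libraries, and its TPM depends on that short span. Tsix, with 5.80 and 13.5 TPM, overlaps Xist on the other strand, and without a stated strand setting the reads of the pair cannot be told apart.

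Each gene list was compared between the libraries by the median log2 ratio of replicate 2 over replicate 1 among its members. Of 32 lists with enough members, 18 lay outside the central 95% of expression-matched random lists, 12 higher in replicate 2 and 6 lower. Choroid plexus genes had the highest median, 0.87, with 9 of 9 members higher and their intervals disjoint; Ttr had 533 TPM in replicate 1 and 1022 in replicate 2. Hox groups 5 to 8 had a median of 0.60, again with 9 of 9 members higher and disjoint, such as Hoxa7 with 7.69 and 15.3 TPM and Hoxb6 with 66.9 and 107, while Hox groups 1 to 4 had 0.18 with 10 of 11 higher. The other lists on that side were skeletal muscle at 0.44 with 5 of 6 members higher, the rhombic lip list at 0.39 with 12 of 15, epithelial genes at 0.38 with 3 of 4, microglia at 0.21 with 9 of 10 and immediate early genes at 0.15 with 7 of 8. Members went both ways among progenitors, at 0.12 with 9 higher and 4 lower, hindbrain factors, at 0.10 with 14 higher and 6 lower, and erythroid genes, at 0.08 with 6 higher and 4 lower. Structured RNAs had 0.14 with 2 of 3 higher, and -0.037 without the filter on low values. The structured RNA and erythroid medians were inside the central 95% when the random lists were not matched on expression.

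Lists with a lower median in replicate 2 were those of cartilage at -0.53 with 4 of 4 members lower, serotonergic and noradrenergic genes at -0.43 with 7 of 10, sex chromosome genes at -0.33 with 4 of 5, ventral patterning genes at -0.29 with 8 of 9, meningeal and mesenchymal genes at -0.26 with 9 of 10 and long noncoding RNAs at -0.16 with 7 of 9. In the serotonergic and noradrenergic list, Slc6a2, the noradrenaline transporter, was higher in replicate 2, with 1.00 and 2.09 TPM and disjoint intervals. Dbh, which makes noradrenaline and was picked after its values were seen, had 1.52 and 2.51 TPM with overlapping intervals. Gata3, a factor of serotonergic and V2 neurons, had 48.4 TPM in replicate 1 and 26.2 in replicate 2, Dbx1 23.4 and 11.6, and Col1a1 176 and 104. Among the sex chromosome genes, Xist, which silences one X chromosome in females, had 12.3 and 22.5 TPM. The Y-linked genes Eif2s3y with 44.8 and 34.4, Uty with 11.2 and 8.65, Kdm5d with 10.9 and 7.59 and Ddx3y with 13.8 and 11.97 were lower in replicate 2. Intervals were disjoint for 4 of these 5 genes, Ddx3y being the exception. Inside the central 95% lay the medians of postmitotic neurons at -0.03, cell cycle genes at -0.05, widely expressed genes at -0.01, endothelial genes at 0.02, pericytes at -0.0023, oligodendrocyte lineage genes at -0.09, sensory ganglion genes at 0.05, cholinergic genes at 0.07, GABAergic genes at 0.08, astrocyte genes at 0.10, midbrain genes at -0.08, border genes at -0.02, forebrain factors at -0.29 and isoform genes at 0.01. Over all genes the median was -0.014. The glutamatergic list and Hox groups 9 to 13 had too few members for this comparison.

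**Figure D3:**
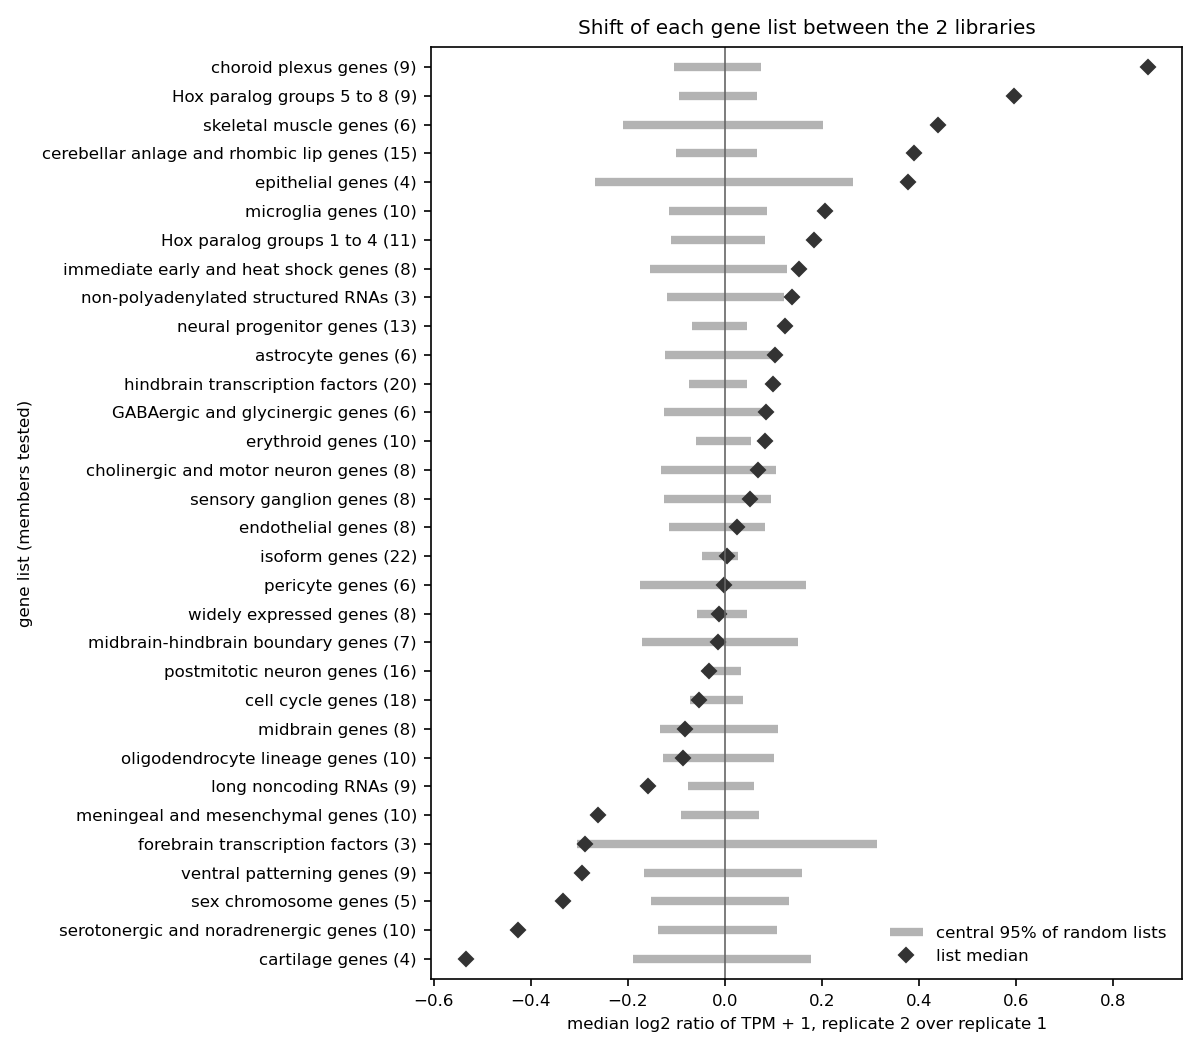
The median log2 ratio of TPM + 1, replicate 2 over replicate 1, is plotted for each of 32 gene lists as a diamond, with a grey bar for the central 95% of 10000 expression-matched random lists. Choroid plexus genes lie farthest to the right at 0.87 and cartilage genes farthest to the left at -0.53.

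Transcript usage was compared for genes with more than 1 annotated transcript. The leading transcript was the same in both libraries for 9389 of 10272 genes, 91.4%. Of 19 isoform genes with more than 1 transcript, 17 kept the leading transcript, with Meis2 and Tpm1, a tropomyosin, the exceptions. The leading transcript carried 47.6% ± 1.71 of Mapt, the microtubule protein tau, 40.4% ± 1.78 of the splicing regulator Ptbp1, 97.9% ± 0.587 of the neuronal splicing factor Srrm4 and 68.8% ± 0.247 of Rbfox2 (SD, n = 2). Cdc42, a small GTPase with alternative last exons, divided into 53.0% ± 1.48 and 47.1% ± 1.48 (SD, n = 2). For Gad1 the leading transcript, 62.0% ± 0.622, is annotated as a processed transcript, ahead of a protein-coding one at 17.3% ± 1.05 (SD, n = 2). Nfia had the widest spread, 51.6% ± 7.80 (SD, n = 2). These shares are estimates from reads that several transcripts can share.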

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

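Rows that carry only a number as identifier entered none of the comparisons and still held reads in both libraries: 27.6 estimated counts over 7 rows in replicate 1 and 23 over 9 rows in replicate 2, above the 3 counts that an observation of 0 allows. They amounted to 15.3 and 15.5 TPM. The 26248 such rows have lengths of 61 to 259 nt. Only 63 of them exceed a minimum length that was assumed here for an effective length above 0. Whether the others can receive a TPM was not checked. No explanation was tested for these counts.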

How the results depend on the processing

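The count of detected genes (15342) ranged from 11293 at a TPM minimum of 5 to 18810 with the posterior mean TPM, and the count of lists outside the central 95% of random lists (18 of 32) from 17 to 20; removal of the trend on length, GC content and expression, which gave 19, was chosen after seeing the data. The cause of the changes below was not tested.

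The replicate correlation was 0.966 with a pseudocount of 0.1, 0.992 without a filter, 0.990 with FPKM and 0.996 with CPM. Genes 2-fold apart numbered 396 with a pseudocount of 0.1, 377 without a filter, 46 at a mean TPM of 5 or more and 50 with CPM. The correlation and the count with CPM both had 1 added to CPM, which shrinks differences of genes with few counts. The coefficient of variation was 0.0631 without a filter, and 0.0001 as the square root of the median gene-wise dispersion of DESeq2, which is the lower bound that tool uses. The hindbrain minus forebrain difference was 5.61 with a pseudocount of 0.1, 3.47 with FPKM, 3.71 with the posterior mean TPM, 4.69 with CPM and 3.60 with list means; in the same order, Hox groups 1 to 4 minus 9 to 13 gave 6.75, 2.996, 3.52, 3.83 and 3.29. With CPM, Hox groups 1 to 4 minus 5 to 8 gave -0.28, neurons minus progenitors 2.58 and the Slc17a6 ratio 0.91; neurons minus progenitors was 2.30 with list means. The share of genes with the same leading transcript was 94.3% at a gene TPM of 10 or more, 86.4% without a filter and 97.4% where the lead was 20 points. Spike-in correlation was 0.995 with a pseudocount of 0.1 and 0.993 with estimated counts.

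As shares of estimated counts, mitochondrial genes took 1.80%, ribosomal protein genes 1.53%, spike-ins 2.43%, haemoglobin genes 0.430% and the 10 highest genes 5.25%; as shares of TPM within Ensembl genes these were 3.75%, 4.42%, 1.43% for haemoglobin and 9.79% for the 10 highest. With the posterior mean TPM, the level of 41 of the named genes moved by more than 1 SD and that of 134 did not. The median of the structured RNAs changed sign without a filter, to -0.037. The forebrain and astrocyte lists crossed the limit of random lists outward under at least 1 alternative, as did the GABAergic list, and the erythroid and structured RNA lists crossed it inward without expression matching. In each library alone the hindbrain minus forebrain difference was 3.86 to 4.09, Hox groups 1 to 4 minus 9 to 13 3.55 to 3.64, neurons minus progenitors 2.84 to 2.90 and the Slc17a6 ratio 0.26 to 0.38. With 2 libraries of 1 group no paired analysis was possible because there is no second group.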

Other observations

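Before their results were seen, tests were set for the second choroid plexus list and for the X-linked genes; the other tests in this part were chosen after the results were seen.

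Choroid plexus genes were higher in replicate 2, with a median log2 ratio of 0.87 over 9 genes. A candidate explanation is that replicate 2 held more choroid plexus tissue. A second list of choroid plexus genes without members of the first had 11 of 11 tested genes higher, 5 of them with disjoint intervals, and a median of 0.30 that lay above all of 10000 matched random lists; values ran from Slc4a5, a bicarbonate transporter, with 1.90 and 4.39 TPM to Slc29a4 with 62.98 and 63.25 TPM. GC content, gene length and expression are argued against by the 50 genes nearest to each member in these properties, with a median of -0.029. Removal of a linear trend left 0.86 but moved no gene by more than 0.033, so it decides nothing. The median over all genes, -0.014, cannot test the scaling of the libraries, since TPM has the same total in each library. A common scale factor would move list members and matched genes alike, and so would not part them. What stays open is whether the amount of tissue, its state or a technical step differed between the libraries, which 2 libraries cannot separate.

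Hox groups 5 to 8 were higher in replicate 2 by a median of 0.60, and the genes matched on GC content, length and expression had -0.023, which argues against these properties, while removal of the linear trend left 0.59 and again decides nothing. A different caudal limit of the dissection may be the source, but it could not be decided from the other genes of the clusters. The test as first set, on genes inside the clusters from group 5 to group 9, had 0 genes with a mean TPM of 1 or more. It was then widened to genes overlapping the clusters, after some of their values had been seen; the 3 tested genes, Hoxb5os, Hoxd3os1 and Hoxaas3, had a median of 0.58. All 3 share positions with listed Hox genes and the strand setting is not given, so their reads are not independent of the pattern and the explanation stays open.

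Xist was higher and 4 Y-linked genes were lower in replicate 2. Counting error is argued against by the disjoint intervals of 4 of the 5 genes, although intervals of 1 library do not cover the spread between pools. A larger share of female embryos in the second pool is a possible explanation, since the labels give pools of both sexes. The 4 X-linked genes that escape inactivation, Ddx3x, Eif2s3x, Kdm5c and Kdm6a, had a median of -0.018 with 2 higher and 2 lower, and members that go both ways decide nothing. The sex ratio of the pools cannot be told apart from other differences between the libraries, technical ones included.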
